A study of Caenorhabditis elegans with 18 samples.

How the data were processed

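RNA from whole Caenorhabditis elegans was measured by RNA sequencing in 18 libraries, which the labels place in 6 groups of 3. Worms carried a mutation in daf-10, which encodes a protein of intraflagellar transport in sensory cilia, or in eat-2, which encodes an acetylcholine receptor subunit needed for pharyngeal pumping. Per the labels' protocols, worms fed on RNAi bacteria from the egg to day 1 of adulthood at 20 °C, with bacteria carrying the empty vector, an atfs-1 construct or a dve-1 construct. Worms were washed and frozen, and RNA was extracted with Tri-Reagent and a column kit. Library kit, strand marking, aligner and counting program are not given in the sources used here.

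The authors deposited 4 tables, each holding 3 empty-vector libraries and 3 libraries of an RNAi treatment in the same mutant. Per the file headers, the deposited counts are mapped reads per WormBase gene of release WS289. They were whole numbers whose totals differed between libraries, and they were used as deposited. Each table also holds the authors' log2 fold change, p-value and adjusted p-value for each gene. The program behind the authors' deposited p-values is not given in the sources used here, and those columns were used only to count calls. The empty-vector counts shared by 2 tables of a genotype were identical for every shared gene. The tables together listed 25826 genes, and 4951 genes that at least 1 table left out were set to a count of 0 there. Gene positions come from the WBcel235 annotation of Ensembl release 115, in which 25818 of the WormBase identifiers were found, each on the chromosome that the deposited tables give.

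Total counts ranged from 26.54 to 36.5 M per library, and 19227 to 20348 genes had at least 1 read. Ribosomal RNA genes took 0.474% to 1.643% of the counts. Replicates of a group correlated at 0.9966 to 0.9983 across genes on a log scale. The chi-square per gene between replicates was 4.24 to 17.18, so no pair of libraries was within sampling noise of being the same library. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

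Differences were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with TMM scaling and edgeR's default low-count filter. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Each comparison used only its own 6 libraries, without a block for the replicate number. RNAi treatments were compared with the empty vector in each mutant and with each other in each mutant. Whether the response differed between mutants was tested as an interaction over 12 libraries, as the eat-2 effect minus the daf-10 effect. TMM factors lay between 0.968 and 1.036 in the 4 comparisons with the empty vector. Levels are CPM, counts scaled to a common library total, with the SD of 3 libraries, and SE is the standard error of the log2 fold change.

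A set of 31 gene lists was tested with limma 3.58.1 by camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Lists were also tested by camera with a correlation estimated from the data and by fry. Of the names on the lists, 9 were not found and 2 were found through a synonym. The design, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. List tests were planned only for the 4 comparisons with the empty vector. Testing the lists in the direct and interaction comparisons was decided after seeing the data. That rule takes dve-1, atfs-1, hsp-6, hsp-60 and dnj-10. It adds the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups. It also takes the 2 members of lowest adjusted p from each list with at least 3 called members, and 3 genes per direction in the direct and interaction comparisons. Members named because a count on a list was 5 or fewer were chosen after their values were seen, and those outside the rule, like the direct values of hsp-6, hsp-60 and the hsp-16 genes, were not refitted without each library.

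The procedure was tested on simulated data drawn from the means and library sizes of each comparison, with 50 genes changed at each fold size, as many up as down. In the real comparisons with the empty vector 20.7% and 20.6% of genes were called in daf-10 and 69.9% and 62.8% in eat-2 (dve-1 label, then atfs-1 RNAi). The simulated shares below therefore need not hold where so many genes change. For the libraries labelled dve-1 RNAi in daf-10, over 15272 genes, 66% of 1.5-fold changes and 90% of 2-fold changes were recovered. Of these calls 9.09% were false. With the atfs-1 construct in daf-10, over 15199 genes, 68% and 84% were recovered at those sizes, and 5.1% of the calls were false. For the libraries labelled dve-1 RNAi in eat-2, over 16029 genes, 78% and 84% were recovered, with 4.43% false calls. With the atfs-1 construct in eat-2, over 15956 genes, 68% and 100% were recovered, with 4.27% false calls. The direct comparisons recovered 60% and 76% in daf-10 and 70% and 90% in eat-2, with 1.43% and 6.33% false calls. The interactions recovered fewer changes: 56% and 62% for the dve-1 label and 48% and 68% for the atfs-1 construct, with 9.76% and 7.76% false calls. In each of the 4 simulations with the empty vector the list that was shifted was called and 0 of the 30 other lists were, by camera with the preset correlation. Simulated genes were drawn independently, so this cannot show how camera behaves where the genes of a list vary together. Wrong splits of the real libraries gave up to 14, 12, 14 and 15 lists (dve-1 label and atfs-1 RNAi in daf-10, then in eat-2). Wrong splits keep part of the real difference, so these are not numbers for groups without a difference.

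Overlaps between RNAi treatments of a genotype share empty-vector libraries, so unchanged groups that share controls were simulated in 100 draws. All libraries of a genotype, the empty-vector ones included, were drawn from the mean empty-vector levels, each gene independently. The alternatives tried were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, the replicate number as a block, a fit over all libraries of a genotype or over all 18, a minimum log2 fold change of 1, and leaving out each library. Upper-quartile scaling and a fit without the lists linked to stage were added after seeing the data. Alternatives planned for values other than counts were not run, since the tables hold counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.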

Results

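Transcript levels were measured in day 1 adult worms of 2 long-lived mutants, daf-10(p821) and eat-2(ad465), after feeding RNAi against dve-1 or atfs-1. ATFS-1 is the bZIP transcription factor that turns on the mitochondrial unfolded protein response (UPR), and DVE-1 is a homeodomain protein that acts with it on mitochondrial chaperone genes. The comparisons ask which transcripts depend on either factor in each mutant, and whether the answer differs between the RNAi labels and between the mutants. There were 3 libraries in each of 6 groups, with 26.54 to 36.5 M counts per library. The first principal component held 78.7% of the variance and the second held 11%. On the first, the empty-vector libraries of eat-2 lay at 89.6 to 91.32 and its RNAi libraries at 22.45 to 36.84. The same empty-vector libraries serve both eat-2 comparisons. In daf-10 the ranges were -33.68 to -29.52 and -64.22 to -50.96.

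The targeted genes were examined first. The transcript of dve-1 (WBGene00022861; WBcel235 chromosome X, 427035 to 433812, a protein-coding gene) was higher, not lower, in the libraries labelled dve-1 RNAi. In daf-10 worms it stood at 29.6 ± 1.03 CPM (SD, n = 3) in these libraries, at 15.2 ± 0.604 CPM with the empty vector and at 13.9 ± 0.989 CPM with atfs-1 RNAi. In eat-2 worms the levels were 44.5 ± 0.832, 31.3 ± 2.87 and 24.5 ± 0.647 CPM. The log2 change against the empty vector was 0.96 (SE 0.07; edgeR adjusted p = 1.73e-08) in daf-10 and 0.45 (SE 0.08; adjusted p = 1.86e-05) in eat-2, and all 3 libraries of each group lay above their controls. The counts therefore go against the label of these libraries. Each direction given for them below is a direction in libraries labelled dve-1 RNAi, not in worms shown to have less dve-1 transcript.

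The transcript of atfs-1 (WBGene00013878; chromosome V, 14193663 to 14197700, a protein-coding gene) fell in the libraries labelled atfs-1 RNAi. It went from 109 ± 1.18 to 72.9 ± 2.89 CPM in eat-2 (log2 -0.55, SE 0.05; edgeR adjusted p = 6.24e-08). In daf-10 it went from 116 to 121 CPM over its 3 libraries to 107 ± 1.86 CPM (log2 -0.15, SE 0.04; adjusted p = 0.00697), a call that was lost in the fit over all 9 libraries of the genotype (adjusted p = 0.0695). In the libraries labelled dve-1 RNAi, atfs-1 stood at 133 ± 8.13 CPM in daf-10 and 120 ± 1.96 CPM in eat-2, with edgeR adjusted p of 0.0761 and 0.23. The first of these passed the test without daf-10_dve1 replicate 2 (adjusted p = 0.00314) and with the replicate number in the model (adjusted p = 0.031), and the second with DESeq2 size factors (adjusted p = 0.0382) and by DESeq2 (adjusted p = 0.0269). With atfs-1 RNAi, dve-1 fell by 0.32 on the log2 scale in eat-2 (SE 0.08; adjusted p = 0.00154), while the value in daf-10 was -0.12 (SE 0.08; adjusted p = 0.295).

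**Figure D1:**
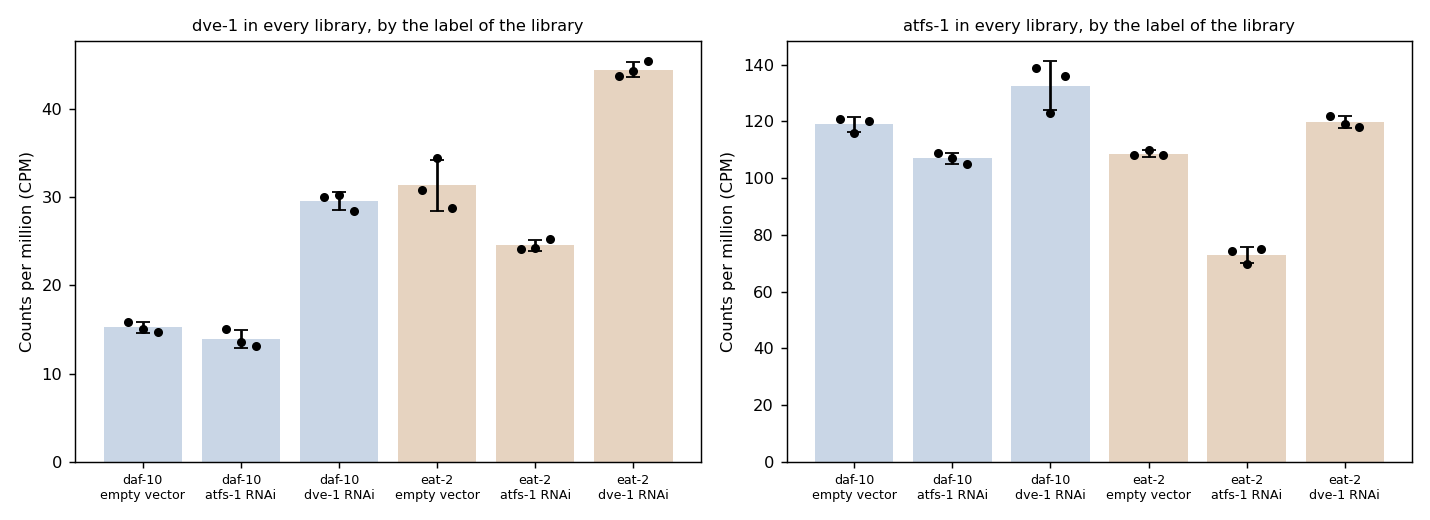
CPM of dve-1 and atfs-1 in the 6 groups; bars are means, error bars are SD and each point is 1 of 3 libraries. The libraries labelled dve-1 RNAi have the highest dve-1 levels of their genotype (29.6 and 44.5 CPM), and those labelled atfs-1 RNAi have the lowest atfs-1 levels (107 and 72.9 CPM).

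In daf-10 worms, the libraries labelled dve-1 RNAi had far more transcript of a few genes and less of many cuticle and sperm genes than the empty vector. The neighbouring genes pud-4 (WBGene00017498; V, 2326678 to 2327282) and pud-3 (WBGene00017501; V, 2324634 to 2325152) rose most among called genes with a mean of at least 5 CPM and no overlap between groups, the limit kept for each ranking below, from 0.804 ± 0.296 to 15 ± 2.76 CPM (log2 4.2, SE 0.18) and from 2.18 ± 0.382 to 38.5 ± 8.42 CPM (log2 4.15, SE 0.15). K02E10.4 rose by 2.62 (SE 0.13), the infection response gene irg-5 by 2.05 (SE 0.13) and the aspartyl protease gene asp-14 by 2.02 (SE 0.07). The largest falls were in the cytochrome P450 gene cyp-13A7 (-2.45, SE 0.14) and in the collagen genes col-7 (-2.29, SE 0.11), col-146 (-2.22, SE 0.09), col-137 (-2.14, SE 0.13) and col-161 (-2.13, SE 0.10). The mitochondrial chaperone genes hsp-6 (HSP70 family), hsp-60 and dnj-10 did not pass the test, with log2 values of -0.06, -0.09 and 0.12 (edgeR adjusted p = 0.504, 0.296 and 0.119).

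Genes expressed in sperm, in the cuticle and during molting fell together in this comparison. Of 56 sperm genes 52 fell and the rest were not called (53 fell adjusted over the list alone), with a median log2 change of -1.28 (camera adjusted p = 5.07e-28). Examples are msp-59 (-1.38, SE 0.08) and msp-53 (-1.50, SE 0.09), which encode major sperm proteins and share reads with near-identical copies. Among 125 cuticle collagens, 77 fell and 7 rose (82 and 11 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 7.44e-16), among them col-13 (-1.98, SE 0.08) and col-73 (-1.69, SE 0.07). Of 30 molting cycle genes 17 fell (20 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 6.42e-07) and with dpy-13 (-1.62, SE 0.08) and sqt-2 (-1.32, SE 0.12) as examples. Germ line, oocyte and eggshell genes moved the other way, with 5 of 39 rising over all genes and adjusted over the list alone and a median of 0.13 (camera adjusted p = 1.3e-05). These were cav-1 (0.46, SE 0.07), perm-4 (0.28), perm-2 (0.27), meg-3 (0.23) and mex-3 (0.21); perm-4 lost its call without daf-10_EV replicate 2 (adjusted p = 0.0549). With an estimated correlation, adjusted p = 0.768 for each of these 4 lists. The 6 vitellogenins, which encode yolk proteins, had a median of 0.06 (camera adjusted p = 0.688); edgeR called 0 of them, also 0 at an unadjusted p under 0.05, and DESeq2 called 0.

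The intestine, C-type lectin, UDP-glucuronosyltransferase and lipid metabolism lists were also lower in these libraries, in which the sperm and cuticle lists fell as well. Of 21 intestine genes 9 fell (12 fell and 1 rose adjusted over the list alone, median -0.19, camera adjusted p = 0.00385), including the intermediate filament gene ifb-2 (-0.51, SE 0.06) and the peptide transporter gene pept-1 (-0.45, SE 0.06). Among the C-type lectins 42 fell and 11 rose (45 and 12 adjusted over the list alone, median -0.24, camera adjusted p = 0.00385), with clec-73 at -1.67 (SE 0.11) and clec-52 at 1.56 (SE 0.08). Of 62 UDP-glucuronosyltransferases 18 fell, such as ugt-63 (-0.85, SE 0.11), and ugt-5 (0.51) and ugt-50 (0.27) rose (23 and 5 adjusted over the list alone, median -0.20, camera adjusted p = 0.0137). The lipid metabolism list of 50 had 15 falls, among them the lipid-binding protein gene lbp-7 (-1.23, SE 0.12) and the lipase gene lipl-5 (-0.50, SE 0.05), and rises in acox-1.2 (0.63), lbp-8 (0.84), acox-1.3 (0.53) and lbp-1 (0.25) (20 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.0416). Of 18 zygotic embryo genes ref-1 (0.46), cnd-1 (1.03) and ceh-36 (1.05) rose and elt-7 (-0.42) fell, the same counts as adjusted over the list alone (median 0.18, camera adjusted p = 0.0416). The calls of ref-1 and elt-7 were lost without daf-10_dve1 replicate 1 (adjusted p = 0.0617 and 0.0542), that of ref-1 also without daf-10_EV replicate 1 or 2 (0.0674 and 0.0838), and that of elt-7 without daf-10_EV replicate 3 (0.0716). These 5 lists had adjusted p = 0.768 with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.15 over 78 genes (camera adjusted p = 1.57e-05, and adjusted p = 0.769 with an estimated correlation). Of these 9 fell, and 0 were called by edgeR when adjusted over the list alone, against 38 at an unadjusted p under 0.05 and 17 by DESeq2.

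The list of mitochondrial UPR chaperones, proteases and import factors was not called in daf-10 with the dve-1 label. Of its 16 members only tin-44 was called (0.17, SE 0.06; edgeR adjusted p = 0.0385), and the median was -0.02 (camera adjusted p = 0.893). Adjusted over the list alone edgeR called 0 members, against 2 at an unadjusted p under 0.05 and 1 by DESeq2 over all genes. In all, 3188 of 15390 genes were called, 876 higher and 2312 lower, and the authors' deposited table gives 829 higher and 1939 lower at its adjusted p of 0.05. With upper-quartile scaling, chosen after seeing the data, 445 were higher and 2538 lower, so that 14.9% rather than 27.5% of the calls were rises. Of the 31 lists 10 were called by camera, 2 up and 8 down.

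With atfs-1 RNAi in daf-10, some mitochondrial lists were slightly lower and the intracellular pathogen response, glutathione and autophagy lists higher than with the empty vector. Y37H2A.14 (WBGene00045416; V, 18143745 to 18144720) rose from 0.941 ± 0.207 to 10.4 ± 0.491 CPM (log2 3.46, SE 0.15) and warf-1 (WBGene00000190; IV, 7634786 to 7635712) from 1.01 ± 0.153 to 10.9 ± 0.418 CPM (log2 3.43, SE 0.14). F15B9.6 (1.90, SE 0.12), Y113G7A.22 (1.76, SE 0.05) and comt-3 (1.67, SE 0.08) followed. The largest falls above the 5 CPM limit were in rips-1 (WBGene00019963; V, 3772021 to 3774609), from 45 ± 3.20 to 6.73 ± 0.449 CPM (log2 -2.73, SE 0.08), and in asp-8 (-2.56, SE 0.13), chca-1 (-2.23, SE 0.07), E01G4.6 (-2.16, SE 0.08) and C02E7.7 (-2.06, SE 0.13). The chaperone gene hsp-6 fell by 0.16 (SE 0.04; edgeR adjusted p = 0.00457), a call lost without daf-10_atfs1 replicate 2 (adjusted p = 0.057). The value of hsp-60 was -0.06 (SE 0.05; adjusted p = 0.37; without daf-10_atfs1 replicate 3 it passed at 0.0408). That of dnj-10 was -0.11 (SE 0.04; adjusted p = 0.0495), a call that every other setting lost except upper-quartile scaling, with adjusted p of 0.186 by DESeq2.

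Several mitochondrial lists were called lower by camera in this comparison. The nuclear-encoded respiratory chain was not, with a median of 0 over 41 genes, 3 of them lower (camera adjusted p = 0.926). Over all genes 2304 of 15357 fell, a larger share than on the mitochondrial ribosome list below. Of the 16 mitochondrial UPR genes 8 fell (8 fell and 1 rose adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0234, and adjusted p = 0.365 with an estimated correlation). DESeq2 called 4 of the 16 over all genes. The call of Y22D7AL.10 was lost without daf-10_EV replicate 2 (edgeR adjusted p = 0.0511) and without daf-10_atfs1 replicate 1 or 2 (0.0535 and 0.0592). Among 11 genes encoded in mitochondrial DNA, 9 fell over all genes and over the list alone, with a median of -0.24 (camera adjusted p = 0.00142, and adjusted p = 0.391 with an estimated correlation), such as nduo-1 (-0.43, SE 0.04) and ctb-1 (-0.25, SE 0.05). The 70 mitochondrial ribosomal protein genes had a median of -0.06 (camera adjusted p = 0.0444, and adjusted p = 0.558 with an estimated correlation). Of these mrps-27 (-0.18), mrpl-35 (-0.25), mrps-26 (-0.13), mrps-33 (-0.20) and mrpl-12 (-0.16) fell, and 0 were called by edgeR when adjusted over the list alone, against 12 at an unadjusted p under 0.05 and 1 by DESeq2 over all genes. The calls of mrps-27 and mrpl-35 were lost without daf-10_EV replicate 2 (adjusted p = 0.0763 and 0.054) or without daf-10_atfs1 replicate 1 (0.14 and 0.0778), and that of mrpl-35 also by DESeq2 (0.0773).

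The intracellular pathogen response, glutathione, autophagy, proteasome and small RNA lists were called higher by camera with atfs-1 RNAi in daf-10. Over all genes 863 of 15357 rose, a larger share than on the proteasome list. Other stress lists were not called: the endoplasmic reticulum UPR list had 9 falls and 1 rise among 25 (camera adjusted p = 0.314), and the cytosolic heat shock list 6 falls and 3 rises among 18 (camera adjusted p = 0.848). Of 23 intracellular pathogen response genes 8 rose and pals-39 (-1.17, SE 0.37) fell (10 and 2 adjusted over the list alone, median 0.30, camera adjusted p = 0.000498, and adjusted p = 0.322 with an estimated correlation). Examples are pals-23 (0.74, SE 0.08) and the ubiquitin ligase subunit gene skr-3 (0.46, SE 0.05). Among 52 glutathione and detoxification genes, 12 rose, such as gst-38 (2.53, SE 0.20) and gst-1 (0.54, SE 0.04), and gst-19 (-1.22) and prdx-3 (-0.16) fell (14 and 2 adjusted over the list alone, median 0.12, camera adjusted p = 0.000269, and adjusted p = 0.324 with an estimated correlation). Of 57 autophagy and lysosome genes 11 rose, such as the autophagy receptor gene sqst-1 (0.62, SE 0.05), and cpr-4 (-0.41, SE 0.04) fell, the same counts as adjusted over the list alone (median 0.04, camera adjusted p = 0.000546, and adjusted p = 0.322 with an estimated correlation). The 33 proteasome genes had a median of 0.05 (camera adjusted p = 0.000498, and adjusted p = 0.391 with an estimated correlation), with only pbs-1 called (0.12, SE 0.04). Adjusted over the list alone edgeR called 0 of them, against 6 at an unadjusted p under 0.05 and 4 by DESeq2 over all genes. Of 31 small RNA pathway genes drh-2 (0.49), sid-2 (0.40), sid-3 (0.20), alg-2 (0.16) and sago-2 (0.29) rose (4 adjusted over the list alone, median 0.06, camera adjusted p = 0.000622, and adjusted p = 0.391 with an estimated correlation).

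The lipid metabolism and UDP-glucuronosyltransferase lists fell. The lipid metabolism list had 25 falls and 6 rises among 50 genes, the same counts as adjusted over the list alone (median -0.18, camera adjusted p = 0.00138, and adjusted p = 0.322 with an estimated correlation). The desaturase gene fat-7 changed by -1.77 (SE 0.08) and cpt-5 by -1.43 (SE 0.09). Of 62 UDP-glucuronosyltransferases 18 fell, including ugt-62 (-1.47, SE 0.05) and ugt-19 (-1.42, SE 0.12), and ugt-44, ugt-48, ugt-31, ugt-29 and ugt-24 rose by 0.40 to 0.81 (21 and 6 adjusted over the list alone, median -0.15, camera adjusted p = 0.00936, and adjusted p = 0.322 with an estimated correlation).

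The sperm, cuticle and molting lists fell with atfs-1 RNAi in daf-10 too. Of 57 sperm genes 51 fell (53 adjusted over the list alone, median -0.94, camera adjusted p = 4.61e-19, and adjusted p = 0.365 with an estimated correlation), such as ssp-16 (-1.31, SE 0.11). Among 123 collagens, 82 fell and 7 rose (86 and 7 adjusted over the list alone, median -0.71, camera adjusted p = 2.54e-15, and adjusted p = 0.365 with an estimated correlation). Both col-71 (-1.74, SE 0.07) and col-38 (-1.52, SE 0.07) fell. Of 30 molting genes 24 fell (26 adjusted over the list alone, median -1, camera adjusted p = 6.45e-13, and adjusted p = 0.322 with an estimated correlation). The collagen genes dpy-13 (-1.94, SE 0.07) and sqt-1 (-1.93, SE 0.12) fell among them. Of 39 germ line genes 10 rose (15 adjusted over the list alone, median 0.09, camera adjusted p = 2.38e-06, and adjusted p = 0.322 with an estimated correlation), such as the eggshell genes perm-2 (0.29, SE 0.04) and perm-4 (0.27, SE 0.04). The vitellogenins fell here, with vit-4 (-0.59), vit-3 (-0.57), vit-1 (-0.36) and vit-5 (-0.28) called among 6, also adjusted over the list alone (median -0.32, camera adjusted p = 0.00936, and adjusted p = 0.365 with an estimated correlation); near-identical vit copies share reads. The body wall muscle and pharynx lists were lower as well: 7 of 28 body wall muscle genes fell (8 adjusted over the list alone, median -0.10, camera adjusted p = 0.00936, and adjusted p = 0.564 with an estimated correlation), such as the myosin gene myo-3 (-0.25, SE 0.04). Of 18 pharynx genes 10 fell, also over the list alone (median -0.28, camera adjusted p = 0.00936, and adjusted p = 0.365 with an estimated correlation), such as phat-4 (-0.88, SE 0.11) and tni-4 (-0.27, SE 0.05). In all 3167 of 15357 genes were called, 863 higher and 2304 lower; the authors' deposited table gives 933 and 1778. Camera called 17 of 31 lists, 6 up and 11 down.

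In eat-2 worms the libraries labelled dve-1 RNAi differed from the empty vector in most genes. T22F3.11 (WBGene00020700; V, 3612158 to 3614553) rose from 2.28 ± 0.414 to 94.3 ± 14.7 CPM (log2 5.32, SE 0.13) and the enoyl-CoA hydratase family gene ech-9 (WBGene00001158; IV, 10233310 to 10235329) from 1.59 ± 0.422 to 36.9 ± 2.25 CPM (log2 4.49, SE 0.13). The lectin gene clec-52 (4.12, SE 0.09), the cytochrome P450 gene cyp-35A3 (4.01, SE 0.11) and cest-29 (3.88, SE 0.13) followed. The glutathione S-transferase gene gst-38 (WBGene00001786; V, 15915162 to 15916070) fell from 10.6 ± 0.941 to 0.450 ± 0.132 CPM (log2 -4.59, SE 0.19), followed by F48G7.5 (-4.14, SE 0.09), K01D12.8 (-4.08, SE 0.19), F54D8.10 (-3.63, SE 0.15) and the cuticle gene cut-2 (-3.53, SE 0.11). Among mitochondrial chaperone genes hsp-60 fell from 476 ± 20.0 to 330 ± 26.3 CPM (log2 -0.58, SE 0.07; edgeR adjusted p = 1.75e-07). The value of hsp-6 was -0.21 (SE 0.08; adjusted p = 0.0245), a call lost with DESeq2 (adjusted p = 0.107), with DESeq2 size factors (0.091), and without eat-2_EV replicate 2 (0.094), eat-2_dve1 replicate 1 (0.0568) or eat-2_dve1 replicate 2 (0.175). That of dnj-10 was 0.08 (SE 0.06; adjusted p = 0.256), which passed the test without eat-2_dve1 replicate 3 (adjusted p = 0.035).

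Stage-linked lists moved in eat-2 with the dve-1 label as well. All 60 sperm genes fell, also over the list alone (median -1.14, camera adjusted p = 4.67e-14, and adjusted p = 0.384 with an estimated correlation). The falls of msp-3 (-1.18, SE 0.06) and msp-56 (-1.19, SE 0.07) are uncertain per copy, since they share reads with other msp copies. Of 30 molting genes 29 fell, also over the list alone (median -2.01, camera adjusted p = 1e-10, and adjusted p = 0.384 with an estimated correlation). Deep falls were those of sqt-2 (-2.85, SE 0.08) and wrt-4 (-2.92, SE 0.08). Among 132 collagens, 101 fell and 23 rose, the same counts over the list alone (median -2.17, camera adjusted p = 3.44e-10, and adjusted p = 0.548 with an estimated correlation). The gene col-157 changed by -3.52 (SE 0.08) and col-49 by -3.04 (SE 0.07). Germ line genes rose in 38 of 39 cases, also over the list alone (median 0.61, camera adjusted p = 8.56e-11, and adjusted p = 0.384 with an estimated correlation). They include cav-1 (1.49, SE 0.10) and nos-2 (0.91, SE 0.06). All 6 vitellogenins rose, also over the list alone (median 0.75, camera adjusted p = 0.00146, and adjusted p = 0.449 with an estimated correlation), such as vit-1 (1.09, SE 0.07). Of 14 zygotic embryo genes 10 rose, such as pes-10 (3.06, SE 0.40), and elt-7 (-0.95, SE 0.13) and nhr-25 (-0.79, SE 0.23) fell, the same counts over the list alone (median 0.75, camera adjusted p = 0.00723, and adjusted p = 0.384 with an estimated correlation).

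In these same libraries the cytosolic ribosome, respiratory chain, endoplasmic reticulum UPR, intestine and UDP-glucuronosyltransferase lists fell. Of 78 cytosolic ribosomal protein genes 74 fell (77 adjusted over the list alone, median -0.47, camera adjusted p = 1.18e-08, and adjusted p = 0.631 with an estimated correlation). Low adjusted p-values were those of rpl-11.2 (-0.86, SE 0.07) and rpl-25.1 (-0.79, SE 0.08). Of 41 nuclear-encoded respiratory chain genes 30 fell, such as nduf-6 (-0.41, SE 0.07), and sdha-2 (0.37, SE 0.06) and nduf-2.2 (0.29, SE 0.07) rose, the same counts over the list alone (median -0.23, camera adjusted p = 0.0123, and adjusted p = 0.646 with an estimated correlation). Among 25 genes of the endoplasmic reticulum UPR list, 14 fell and ire-1 (0.34), srp-7 (0.21) and pek-1 (0.27) rose, the same counts over the list alone (median -0.28, camera adjusted p = 0.0246, and adjusted p = 0.543 with an estimated correlation). The falls on that list include abu-7 (-2.62, SE 0.10) and abu-11 (-2.52, SE 0.11), genes known for their induction when that response is blocked, while its kinase genes ire-1 and pek-1 rose. Of 21 intestine genes 18 fell, including pho-1 (-1.74, SE 0.08) and ifc-2 (-1.18, SE 0.06), and gob-1 (0.19, SE 0.07) rose, the same counts over the list alone (median -0.67, camera adjusted p = 0.000453, and adjusted p = 0.384 with an estimated correlation). The UDP-glucuronosyltransferase family had 37 falls and 9 rises among 62, also over the list alone (median -0.53, camera adjusted p = 0.00132, and adjusted p = 0.384 with an estimated correlation). Here ugt-19 had -2.24 (SE 0.10) and ugt-62 had -2.16 (SE 0.07).

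Small RNA and cilium genes rose in eat-2 with the dve-1 label. Of 31 small RNA pathway genes 23 rose, such as the Argonaute gene ergo-1 (0.62, SE 0.07), and sid-2 (-0.79), drh-2 (-0.35), sid-3 (-0.24) and sago-1 (-0.20) fell, the same counts over the list alone (median 0.32, camera adjusted p = 0.000592, and adjusted p = 0.479 with an estimated correlation). Among 34 genes of sensory cilia, 14 rose, such as dyf-11 (1.61, SE 0.17) and osm-1 (0.72, SE 0.10), and ift-74 (-0.59) and che-13 (-0.42) fell (13 and 2 adjusted over the list alone, median 0.32, camera adjusted p = 0.00801, and adjusted p = 0.384 with an estimated correlation). The mitochondrial UPR list was not called: 7 of 16 members fell, among them Y22D7AL.10 (-0.49, SE 0.06), and ymel-1 (0.16, SE 0.07) rose, also over the list alone (median -0.13, camera adjusted p = 0.638). In all 11331 of 16200 genes were called, 5229 higher and 6102 lower, and the authors' deposited table gives 5600 and 5329. DESeq2 size factors in edgeR gave 5770 higher and 5655 lower, and DESeq2 gave 5611 and 5339. Upper-quartile scaling, chosen after seeing the data, gave 4653 and 6574. The balance of rises and falls thus depends on the scaling. Camera called 13 of 31 lists, 5 up and 8 down.

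With atfs-1 RNAi in eat-2, mitochondrial chaperone genes fell. From the empty vector to the knockdown hsp-60 (WBGene00002025; III, 1619742 to 1625803) went from 476 ± 20.0 to 315 ± 11.7 CPM (log2 -0.56, SE 0.06; edgeR adjusted p = 8.74e-08). The transcript of hsp-6 (WBGene00002010; V, 4824124 to 4826760) went from 498 ± 24.5 to 366 ± 5.74 CPM (log2 -0.41, SE 0.05; adjusted p = 2.33e-06), and dnj-10 fell by 0.17 (SE 0.05; adjusted p = 0.00963; 0.0516 by DESeq2). The largest rises above that limit of 5 CPM were in ech-9 (3.53, SE 0.16), T22F3.11 (3.37, SE 0.15), cyp-35A3 (2.87, SE 0.13), the aspartyl protease gene asp-12 (2.71, SE 0.09) and col-95 (2.59, SE 0.08). The largest falls above the 5 CPM limit were in chca-1 (WBGene00044107; IV, 9651394 to 9652480), from 78.8 ± 5.55 to 3.04 ± 0.284 CPM (log2 -4.66, SE 0.09), and in K01D12.8 (-3.89, SE 0.16), B0205.13 (-3.57, SE 0.12), F58G6.3 (-3.26, SE 0.12) and fkb-4 (-3.16, SE 0.14).

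Of the 16 mitochondrial UPR genes 12 fell, such as Y22D7AL.10 (-0.71, SE 0.06), and haf-1 (0.34, SE 0.11) rose, the same counts over the list alone (median -0.23, camera adjusted p = 0.0316, and adjusted p = 0.341 with an estimated correlation). Among 70 mitochondrial ribosomal protein genes, 35 fell, such as mrpl-12 (-0.47, SE 0.06) and mrpl-15 (-0.40, SE 0.06), and mrpl-40 (0.20, SE 0.07) rose (34 and 1 adjusted over the list alone, median -0.16, camera adjusted p = 0.0103, and adjusted p = 0.794 with an estimated correlation). Cytosolic ribosomal protein genes fell in 64 of 78 cases (67 adjusted over the list alone, median -0.21, camera adjusted p = 0.000105, and adjusted p = 0.794 with an estimated correlation), with rpl-11.2 at -0.51 (SE 0.06). The endoplasmic reticulum UPR list had 17 falls among 25, led by abu-11 (-1.76, SE 0.09) and abu-7 (-1.66, SE 0.10), and rises of ire-1 (0.30), srp-7 (0.19) and pek-1 (0.20), the same counts over the list alone (median -0.31, camera adjusted p = 0.00868, and adjusted p = 0.386 with an estimated correlation). Of 126 C-type lectins 64 fell, including clec-265 (-1.65, SE 0.07) and clec-180 (-2.26, SE 0.10), and 25 rose (65 and 25 adjusted over the list alone, median -0.42, camera adjusted p = 0.0326, and adjusted p = 0.386 with an estimated correlation). Of 63 UDP-glucuronosyltransferases 36 fell and 9 rose, also over the list alone (median -0.47, camera adjusted p = 0.00185, and adjusted p = 0.506 with an estimated correlation). The value of ugt-62 was -2.98 (SE 0.07) and that of ugt-19 was -2.86 (SE 0.09). Autophagy and lysosome genes rose in 27 and fell in 8 of 57 cases, also over the list alone (median 0.11, camera adjusted p = 0.00414, and adjusted p = 0.304 with an estimated correlation). Among the rises were the cathepsin genes cpr-1 (1.32, SE 0.06) and cpl-1 (0.65, SE 0.05).

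The stage-linked lists moved in the same libraries. All 6 vitellogenins rose, also over the list alone (median 1.3, camera adjusted p = 5.19e-05, and adjusted p = 0.304 with an estimated correlation). The rise was 1.55 for vit-1 (SE 0.05) and 1.5 for vit-5 (SE 0.06). Vitellogenins took 1.167% ± 0.023 of all counts with the empty vector (SD, n = 3), 2.483% ± 0.121 with atfs-1 RNAi and 1.832% ± 0.075 in the libraries labelled dve-1 RNAi. Of 61 sperm genes 58 fell and nspd-11 (1.01, SE 0.38) rose (59 and 1 adjusted over the list alone, median -1.01, camera adjusted p = 3.67e-15, and adjusted p = 0.341 with an estimated correlation). Among 30 molting genes, 29 fell, including sqt-1 (-2.69, SE 0.07) and dpy-13 (-2.60, SE 0.07), and nas-37 (0.21, SE 0.08) rose, the same counts over the list alone (median -2.21, camera adjusted p = 8.77e-13, and adjusted p = 0.341 with an estimated correlation). Among 131 collagens, 100 fell and 22 rose (101 and 22 adjusted over the list alone, median -1.75, camera adjusted p = 1.52e-10, and adjusted p = 0.506 with an estimated correlation). Changes were -2.35 for col-60 (SE 0.06) and -2.55 for col-38 (SE 0.06). Of 39 germ line genes 37 rose, such as perm-2 (0.82, SE 0.05), and glh-1 (-0.13, SE 0.05) fell (38 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 1.13e-12, and adjusted p = 0.341 with an estimated correlation). Of 21 intestine genes 15 fell, such as pho-1 (-0.86, SE 0.06), and asp-6 (0.22, SE 0.06) rose, the same counts over the list alone (median -0.35, camera adjusted p = 0.0159, and adjusted p = 0.709 with an estimated correlation). Of 31 small RNA pathway genes 24 rose, such as ergo-1 (0.65, SE 0.06) and the RNA channel gene sid-1 (0.57, SE 0.06), and sid-2 (-0.55, SE 0.09) fell, the same counts over the list alone (median 0.27, camera adjusted p = 1.74e-05, and adjusted p = 0.386 with an estimated correlation). In all 10098 of 16081 genes were called, 4701 higher and 5397 lower, and the authors' deposited table gives 4769 and 4759. DESeq2 gave the same counts as that table, and DESeq2 size factors in edgeR gave 5066 higher and 5109 lower. Upper-quartile scaling gave 4130 and 5816, so the excess of falls depends on the scaling here too. Camera called 14 of 31 lists, 4 up and 10 down.

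No list call held with an estimated correlation in any of the 4 comparisons with the empty vector. Camera with that correlation called 0 lists in each, and 0, 3, 1 and 3 lists had an unadjusted p under 0.05 with the dve-1 label in daf-10, atfs-1 RNAi in daf-10, the dve-1 label in eat-2 and atfs-1 RNAi in eat-2. By fry, which asks whether the members of a list move to the same side and does not compare them with other genes, 9, 18, 26 and 22 lists were called. The median, the mean and the test of each list called by camera with the preset correlation had the same sign.

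**Figure D2:**
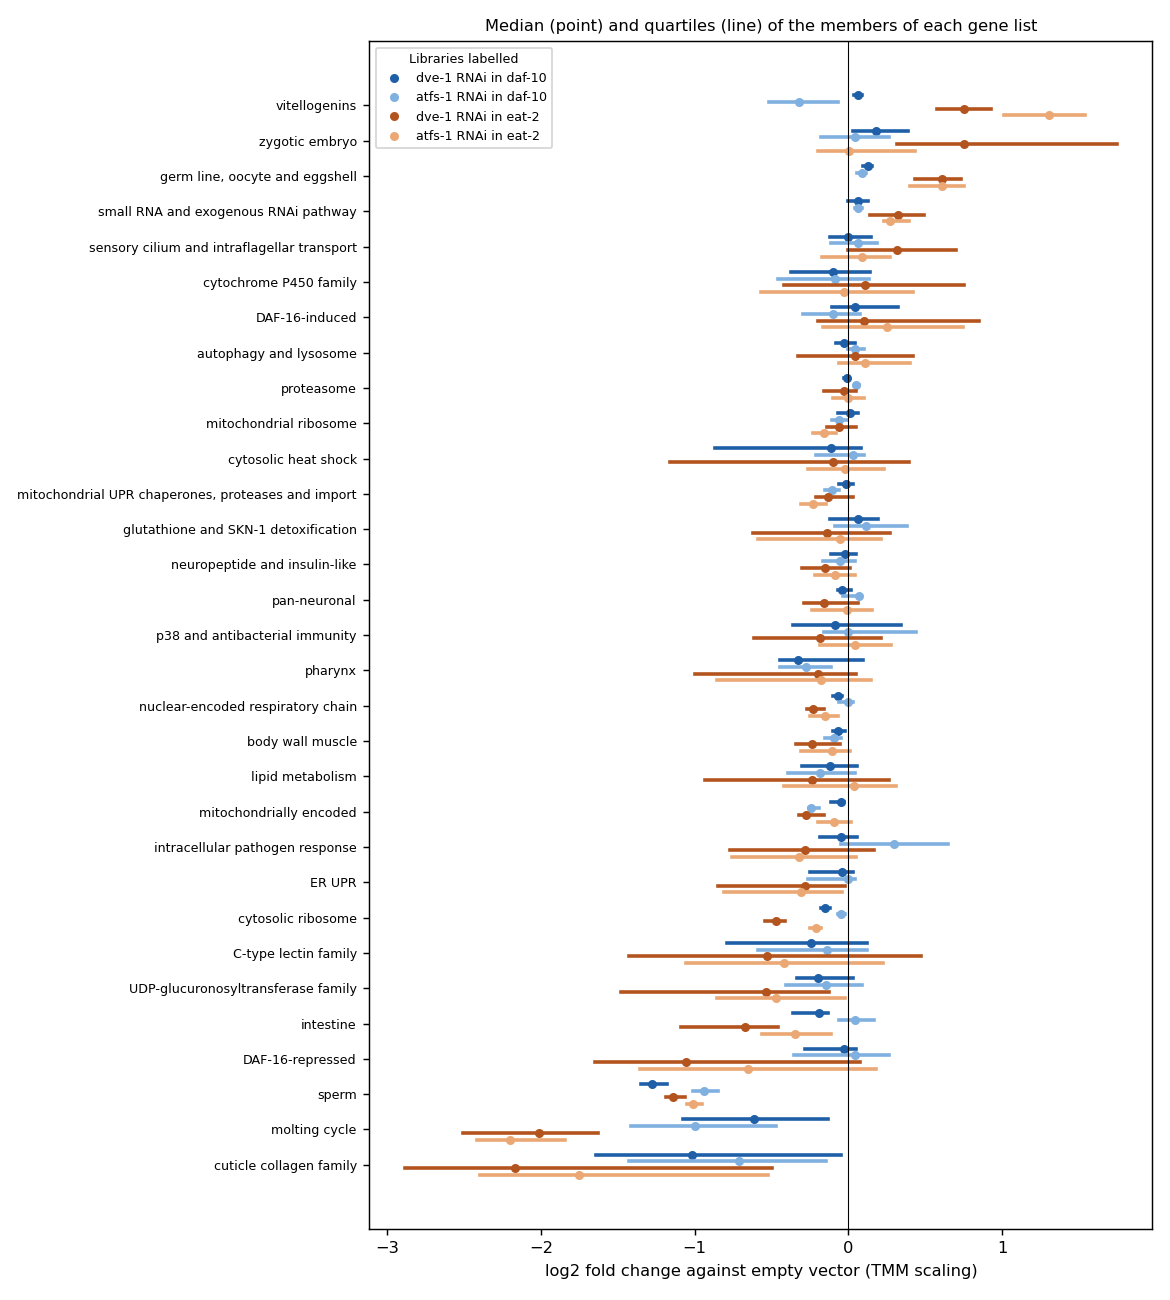
Median log2 fold change against the empty vector for the members of 31 gene lists in the 4 comparisons, with bars from the lower to the upper quartile of the members. The molting cycle medians lie at -0.62 and -1 in daf-10 and at -2.01 and -2.21 in eat-2 (dve-1 label, then atfs-1 RNAi), and the germ line medians lie above 0 in all 4.

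The libraries labelled dve-1 RNAi and atfs-1 RNAi were also compared directly, without the empty-vector libraries. In daf-10, the libraries labelled dve-1 RNAi had higher levels than those of atfs-1 RNAi of pud-4 (log2 3.91, SE 0.17), pud-3 (3.65, SE 0.18) and K02E10.4 (3.25, SE 0.18), and lower levels of warf-1 (-3.69, SE 0.15), Y37H2A.14 (-3.45, SE 0.14) and M01G12.9 (-2.53, SE 0.12). In eat-2, K02E10.4 (4.14, SE 0.12), gst-39 (3.54, SE 0.07) and irg-5 (3.53, SE 0.11) were higher, and F49F1.5 (-3.12, SE 0.16), the tubulin gene tbb-6 (-2.11, SE 0.12) and the folate transporter family gene folt-2 (-2.08, SE 0.06) were lower. Camera called 17 lists in daf-10 and 12 in eat-2, of which some are given here. With the dve-1 label the sperm list was lower in daf-10 and eat-2 (medians -0.35 and -0.13, camera adjusted p = 2.56e-07 and 0.00133). So were the collagens (-0.09 and -0.39, 0.0401 and 7.62e-10) and the cytosolic ribosome (-0.12 and -0.27, 2.56e-07 and 7.68e-11). The molting list was higher in daf-10 (0.35, 5.97e-07) and not called in eat-2 (0.14, 0.136). Each had an adjusted p of at least 0.504 with an estimated correlation. The mitochondrial UPR list was higher with the dve-1 label in both mutants, with 2 of 16 members called in daf-10 (median 0.06, camera adjusted p = 0.037, and adjusted p = 0.504 with an estimated correlation) and 6 of 16 in eat-2 (median 0.13, camera adjusted p = 0.00457, and adjusted p = 0.525 with an estimated correlation). Of its members hsp-6 differed by 0.21 in eat-2 (SE 0.07; edgeR adjusted p = 0.0479) and hsp-60 by -0.01 (SE 0.07; adjusted p = 0.923). Of 6 vitellogenins 3 were called higher with the dve-1 label in daf-10 (median 0.26, camera adjusted p = 0.00205, and adjusted p = 0.504 with an estimated correlation). In eat-2 all 6 were called lower (median -0.47, camera adjusted p = 6.99e-05, and adjusted p = 0.525 with an estimated correlation). Intestine genes were lower in both, with 13 of 21 called in daf-10 (median -0.34, camera adjusted p = 3.67e-06, and adjusted p = 0.504 with an estimated correlation) and 12 of 21 in eat-2 (median -0.33, camera adjusted p = 2.6e-05, and adjusted p = 0.647 with an estimated correlation). In daf-10 1248 of 15102 genes were called, 360 higher and 888 lower with the dve-1 label. In eat-2 3360 of 15926 were called, 1405 higher and 1955 lower, and 2178 without eat-2_dve1 replicate 1. At a log2 difference of at least 1 there were 347 higher and 219 lower in eat-2.

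Direct differences were shared between the mutants, whose libraries are separate. With the dve-1 label 171 genes were higher than with atfs-1 RNAi in both mutants, where independent lists would share 30.1, and 532 were lower in both, where independent lists would share 112.2; 71 genes were called in opposite directions. Across genes, which are not independent replicates, the correlation of the log2 differences was 0.46. Genes called against the empty vector and against atfs-1 RNAi in both mutants numbered 83 that rose and 296 that fell with the dve-1 label. Among the rises were the saposin-like genes spp-12 (4.90, SE 0.39 in daf-10; 7.10, SE 0.28 in eat-2) and spp-9 (3.65, SE 0.50; 6.12, SE 0.68), the lectin gene clec-60 (3.73, SE 0.37; 3.69, SE 0.12) and the nuclear receptor gene nhr-167 (3.23, SE 0.28; 3.88, SE 0.21). In daf-10 these genes missed the ranking limit of at least 5 CPM and no overlap between groups. In eat-2 spp-12 and spp-9 missed it too. Their fold changes may therefore rest on low counts. For atfs-1 RNAi 54 rose and 51 fell in both mutants by the same rule, with rises of tbb-6 (1.92 and 1.1) and falls of chca-1 (-2.23 and -4.66), rips-1 (-2.73 and -1.81) and the collagen gene bli-1 (-1.53 and -2.57). Apart from tbb-6, chca-1 and rips-1, these examples were chosen after their values were seen.

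Calls against the empty vector overlapped between the RNAi labels within a mutant. In daf-10 1885 genes were called in the same direction for both, 190 up and 1695 down, where independent lists would share 47.2 and 349.5; 85 were called in opposite directions. In eat-2 9007 were shared, 4086 up and 4921 down, against 1492.8 and 2061.4, and 96 were opposite. The simulated unchanged groups shared a median of 0 edgeR calls and at most 1 in 100 draws. No gene was changed in these draws and genes were drawn independently, so few calls could arise. That count therefore cannot weigh the shared controls. Part of the excess may come from these controls, which are too few to split. The correlation of log2 changes across genes was 0.76 in daf-10 and 0.88 in eat-2, beside simulated means of 0.51 and 0.50. The covariance was 0.185 and 0.590 beside simulated values of 0.016 and 0.014, a difference of 0.169 and 0.576.

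Responses in libraries with the same RNAi label overlapped between the mutants as well. In the libraries labelled dve-1 RNAi 729 genes rose and 2080 fell in both mutants, where independent lists would share 286.3 and 837.1, and 120 went in opposite directions. With atfs-1 RNAi 420 rose and 1962 fell in both, against 261.9 and 732.7, and 296 went in opposite directions. The shared rises were 241 in the fit over all libraries of a genotype and 524 by DESeq2, so their number depends on the model. The correlation across genes was 0.67 and 0.62. The interaction test called 6410 of 16711 genes for the dve-1 label, 3692 with a higher and 2718 with a lower value in eat-2 than in daf-10. Upper-quartile scaling, chosen after seeing the data, gave 3217 and 2987, so that 51.9% rather than 57.6% were higher. For atfs-1 RNAi it called 6096 of 16601, 3864 higher and 2232 lower, and upper-quartile scaling gave 3083 and 2722, so that 53.1% rather than 63.4% were higher. At a log2 difference of at least 1 the balance turned round, with 537 higher and 1122 lower for the dve-1 label and 341 and 739 for atfs-1 RNAi.

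**Figure D3:**
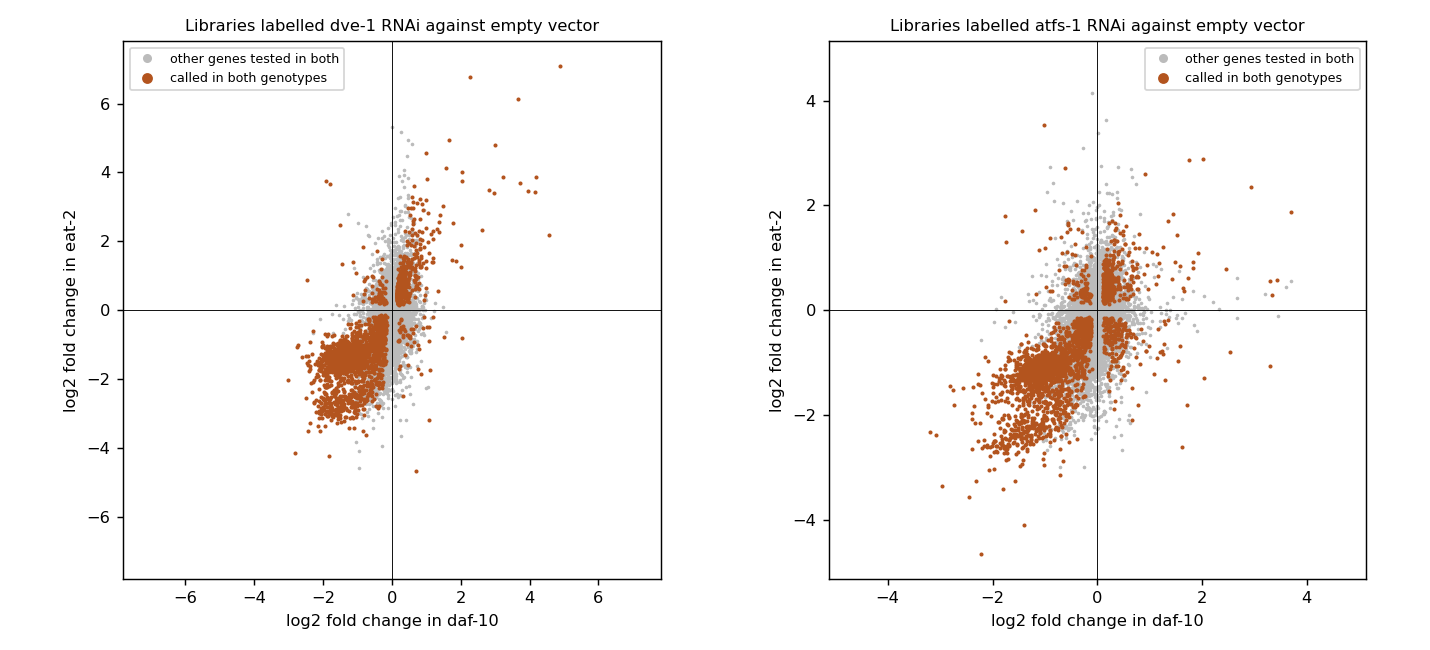
Log2 fold change against the empty vector in daf-10 (horizontal axis) and eat-2 (vertical axis), for the dve-1 label and for atfs-1 RNAi; each point is a gene tested in both mutants, and genes called in both are orange. The correlations across genes are 0.67 and 0.62.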

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

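All tests in this part that weigh an explanation, and all counts of other splits, were put in writing after the results they measure had been seen. The interaction tests of genes were planned, while testing the gene lists for an interaction was decided after seeing the data. The results below stand out because the effect of an RNAi label differed between the mutants in an interaction test over 12 libraries, given as the eat-2 log2 change minus the daf-10 log2 change with edgeR adjusted p-values. That test called 6410 genes for the dve-1 label and 6096 for atfs-1 RNAi. The empty-vector libraries of the 2 mutants already differed in stage-linked genes. Vitellogenins took 4.17% ± 0.098 of their counts in daf-10 and 1.167% ± 0.023 in eat-2 (SD, n = 3). The interaction test does not separate a different response to an RNAi label from a different starting point of the controls. Nor does it separate, for atfs-1 RNAi, a different response from a different depth of knockdown.

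For the dve-1 label the largest positive values among called genes above the CPM limit were those of asp-12 (5.48, SE 0.13), which went from 8.67 ± 0.243 to 2.49 ± 0.164 CPM in daf-10 and from 10.7 ± 1.13 to 141 ± 9.78 CPM in eat-2 (SD, n = 3), T22F3.11 (5.33, SE 0.33) and ech-9 (4.06, SE 0.35). The largest negative fitted values under that limit belonged to Y113G7B.12, clec-10 and K09F6.9, which had at most 7 reads in any daf-10 library, so no fold is given. The next largest, chosen after their values were seen, were gpdh-1, a glycerol-3-phosphate dehydrogenase gene (-3.39, SE 0.19; 12.4 to 14.5 CPM in daf-10, 32.1 to 3.65 CPM in eat-2), C06E4.3 (-2.86, SE 0.30) and F54D8.10 (-2.85, SE 0.25). The value of hsp-60 was -0.48 (SE 0.09; edgeR adjusted p = 0.000303) and that of dve-1 itself was -0.49 (SE 0.11; adjusted p = 0.000998).

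For atfs-1 RNAi the largest positive values under that limit were ech-9 (4.58, SE 0.40), T22F3.11 (3.39, SE 0.32) and asp-12 (3.35, SE 0.14). Y37H2A.14 had -3.54 (SE 0.16), with 0.941 to 10.4 CPM in daf-10 against 20.8 to 18.9 CPM in eat-2, and gst-38 had -3.32 (SE 0.20), with 0.540 to 3.13 CPM against 10.6 to 5.95 CPM. ZC204.12 had at most 2 reads in any daf-10 library and gets no fold; Y41C4A.32 (-3.02, SE 0.25) was named in its place after its value was seen. The target atfs-1 had a lower value in eat-2 than in daf-10 (-0.37, SE 0.06; edgeR adjusted p = 6.05e-05), as did hsp-60 (-0.47, SE 0.08; adjusted p = 4.64e-05), which was not called in daf-10, and hsp-6 (-0.22, SE 0.07; adjusted p = 0.0102).

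Lists that differed between the mutants by camera are given as medians, each followed by its adjusted p with an estimated correlation. For the dve-1 label 10 lists were called: the vitellogenins (0.80, adjusted p = 0.382), molting cycle (-1.36, adjusted p = 0.376), collagens (-0.89, adjusted p = 0.478), germ line (0.49, adjusted p = 0.376), cytosolic ribosome (-0.31, adjusted p = 0.478) and small RNA pathway (0.31, adjusted p = 0.478), and those below. The UDP-glucuronosyltransferases (-0.34, adjusted p = 0.376), intestine (-0.51, adjusted p = 0.376), endoplasmic reticulum UPR (-0.23, adjusted p = 0.478) and nuclear-encoded respiratory chain (-0.12, adjusted p = 0.66) had lower values in eat-2. For atfs-1 RNAi 16 lists were called, and the vitellogenins differed by 1.77, a call that held with an estimated correlation (adjusted p = 0.0471). Other lists were molting cycle (-1.11, adjusted p = 0.154), collagens (-0.75, adjusted p = 0.525), germ line (0.53, adjusted p = 0.127), small RNA pathway (0.26, adjusted p = 0.464) and mitochondrial UPR (-0.08, adjusted p = 0.22). The intracellular pathogen response (-0.59, adjusted p = 0.0642), glutathione and detoxification (-0.24, adjusted p = 0.127) and DAF-16-induced lists (0.43, adjusted p = 0.127) were called by the preset correlation as well. So were the cytosolic ribosome (-0.15, adjusted p = 0.671), intestine (-0.33, adjusted p = 0.399), endoplasmic reticulum UPR (-0.29, adjusted p = 0.269) and UDP-glucuronosyltransferases (-0.23, adjusted p = 0.399). The remaining calls were the mitochondrial ribosome (-0.07, adjusted p = 0.671), nuclear-encoded respiratory chain (-0.10, adjusted p = 0.558) and DAF-16-repressed lists (-0.54, adjusted p = 0.178).

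Other splits of the libraries were counted for each result. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; in each of the 6 such comparisons 1 of the 10 splits, the real one, gave as many genes. The highest of the other splits gave 0 genes by edgeR, with at most 1364, 630, 111 and 224 at an unadjusted p under 0.05 in the comparisons with the empty vector (dve-1 label and atfs-1 RNAi in daf-10, then in eat-2) and 734 and 787 in the direct ones. For the 10, 17, 13 and 14 lists called, 4, 1, 2 and 2 of the 10 splits gave as many, with 14, 12, 14 and 15 lists in the highest other split. Every wrong split sets unequal mixes of the true groups against each other, so part of the real difference stays in it. The counts from wrong splits therefore do not show what groups without a difference would give. For the interactions 13 of 100 relabellings within the mutants gave as many genes for the dve-1 label (highest other 9361) and 7 of 100 for atfs-1 RNAi (highest other 8030), so this count does not exclude chance. All of these kept the true grouping of the eat-2 libraries, whose response stays in the difference, and the relabellings that broke that grouping gave at most 1 and 36 genes.

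The dve-1 counts were higher in the libraries labelled dve-1 RNAi. A swap of labels with the empty vector would put dve-1 higher in the atfs-1 RNAi libraries than in those labelled empty vector, and the higher of the 2 differences was -0.12. A swap with the atfs-1 RNAi libraries would put atfs-1 lower in the libraries labelled dve-1 RNAi, yet it was higher there by at least 0.29. Scaling is argued against too, since the lowest log2 change of dve-1 over 4 scalings and 2 mutants was 0.39. Reads from the RNAi construct itself could raise the count and stay open, as does a response of the gene to RNAi against it, which was not tested; counts per gene do not show where reads lie, and the other target, atfs-1, went the other way in its own libraries (-0.55 in eat-2, and -0.15 in daf-10, where the call was lost in the fit over 9 libraries), which does not decide this.

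The molting, collagen and sperm lists were lower and the germ line list higher in all 4 comparisons with the empty vector. Scaling moves every list alike, and the smallest gap between the germ line and molting medians was 0.75, so it is argued against. A later developmental stage at harvest may explain the pattern in eat-2, because the yolk genes it should raise rose as well, with medians of at least 0.75. In daf-10 with atfs-1 RNAi those genes fell (median -0.32), against the rise that a later stage was taken to give. They already took 4.17% of the counts in daf-10 with the empty vector, beside 1.167% in eat-2. Whether a later stage would raise them further there is not known, so the fall does not decide this. With the dve-1 label the median of 0.06 leaves it open as well. In eat-2 the rise of the yolk genes does not exclude a direct effect of the RNAi treatment. A difference in stage and a direct effect therefore cannot be told apart in either mutant. A biological effect of the RNAi treatments on these tissues at equal stage was not tested.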

How the results depend on the processing

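No call of a named gene reversed under any alternative. Of the values of named genes that were not called, those of atfs-1 (-0.12 to 0.03) and dnj-10 (-0.06 to 0.03) in the interaction for the dve-1 label took both signs over the alternatives. DESeq2 kept 295 of the values of named genes on the same side of the threshold, lost 7 and added 1; DESeq2 size factors in edgeR kept 300, lost 2 and added 1, and fitting without the low-count filter kept 302 and lost 1. The fit over all libraries of a genotype kept 279 and lost 2, and that over all 18 kept 22. Leaving out each library kept 1891, lost 55 and added 4. Requiring a log2 fold change of at least 1 left 1465, 1104, 3906 and 2824 genes (dve-1 label and atfs-1 RNAi in daf-10, then in eat-2), 278 and 566 in the direct comparisons in daf-10 and eat-2, and 1659 and 1080 in the interactions, fewer by construction. Against the empty vector this left 4.98%, 8.33%, 17.6% and 10.3% of the calls as rises. The balance turned round in the direct comparison in eat-2 (347 higher and 219 lower with the dve-1 label) and in the interactions (537 higher and 1122 lower for the dve-1 label, 341 and 739 for atfs-1 RNAi), and in daf-10 the direct comparison gave 108 higher and 170 lower. Leaving out each library gave 2140 to 4119, 2499 to 3218, 10506 to 11139 and 9219 to 9949 genes against the empty vector, 834 to 1624 and 2178 to 3573 in the direct comparisons, and 5904 to 6474 and 5255 to 6095 in the interactions. The low of 2178 came without eat-2_dve1 replicate 1; the cause was not tested. Lists called ranged over 7 to 12, 15 to 19, 12 to 14 and 11 to 14 on leaving out each library. With an estimated correlation camera called 0 lists in each of the 4 comparisons (0, 3, 1 and 3 at an unadjusted p under 0.05), and fry called 9 and 18 lists in daf-10 and 26 and 22 in eat-2; the reason for the larger counts in eat-2 was not tested. Of the named genes near the floor of reads, K09F6.9 and Y113G7B.12 lost their interaction call without daf-10_dve1 replicate 1, K09F6.9 also without each daf-10_EV library and several eat-2 libraries, and with the replicate block (adjusted p = 0.0602), and ZC204.12 without daf-10_atfs1 replicate 2 or 3.

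The replicate numbers do not pair the samples: within a genotype deviations of same-numbered libraries correlated at -0.187 to 0.159, 2 of 18 pairs were over 0.1, and in 5 of 18 pairs the own number matched best. Between genotypes the correlations ran from -0.289 to 0.169. With the replicate block 3811, 2789, 11013 and 9790 genes were called against the empty vector, 1479 and 3043 in the direct comparisons, 6157 and 5854 in the interactions, and 9, 17, 13 and 13 lists. The block kept 298 of the values of named genes, lost 4 and added 1, the call of atfs-1 with the dve-1 label in daf-10 (0.16, adjusted p = 0.031). Genes shared in the same direction, by DESeq2 and by the fit over all libraries of a genotype, numbered 1556 and 1753 between the RNAi labels in daf-10, 8575 and 9044 in eat-2, 2513 and 3050 between the mutants for the dve-1 label, and 2058 and 2023 for atfs-1 RNAi. Upper-quartile scaling and leaving out the lists linked to stage were chosen after seeing the data; they kept 302 and 217 of the values of named genes and lost 1 each. At these depths, 48% of the smallest changes tried were recovered on simulated data with the dve-1 label in daf-10, so smaller changes were not detectable there with certainty.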

Other observations

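The tests of the genes almost without reads in daf-10 were put in writing after the results they measure had been seen. The direct comparisons of genes and the members of the gene lists were planned. Testing the lists in the direct comparisons was decided after seeing the data. The genes named here outside the rule for naming genes were chosen after their values were seen.

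Of the small heat shock genes, hsp-16.41, hsp-16.2 and hsp-12.3 differed between the RNAi labels in both mutants, while the list they belong to was not called. In the libraries labelled dve-1 RNAi, hsp-16.41 fell by 1.22 on the log2 scale in daf-10 (SE 0.08) and had a change of -1.4 in eat-2 (SE 0.12), and hsp-16.2 had changes of -1.26 (SE 0.10) and -1.42 (SE 0.13). With atfs-1 RNAi the values were -0.20 and -0.46 for hsp-16.41 and -0.22 and -0.28 for hsp-16.2. Compared directly, hsp-16.41 was lower with the dve-1 label by -1.04 in daf-10 and -0.94 in eat-2 (edgeR adjusted p = 1.37e-07 and 3.04e-05), and hsp-16.2 by -1.06 and -1.14 (adjusted p = 4.81e-07 and 1.62e-06). The 18 genes of the cytosolic heat shock list had a median of -0.14 in daf-10 (camera adjusted p = 0.0556, and adjusted p = 0.504 with an estimated correlation) and 0.02 in eat-2 (0.65 and 0.825). In daf-10 1 member was called higher and 6 lower with the dve-1 label, and in eat-2 4 higher and 3 lower. Unlike the hsp-16 genes, hsp-12.3 was higher with the dve-1 label, at 1.12 and 1.29 (adjusted p = 1.56e-05 and 2.37e-08). For hsp-70 the direct values were -0.18 and 0.02 (adjusted p = 0.0696 and 0.935). The hsp-16 genes lie in similar copies that share reads, so single members are uncertain.

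A set of genes was almost without reads in every daf-10 library. Of 12710 genes with a mean of at least 2 CPM over the eat-2 libraries, 100 had at most 10 reads in each daf-10 library, 63 of them on chromosome II and 31 on chromosome V, while 4 genes showed the reverse. Lower depth is argued against for genes that hold this level in every eat-2 library, since 2 CPM gives 60.2 reads in the smallest daf-10 library. A strain variant against the reference is a candidate explanation: the longest run of neighbouring genes in the set held 13, from math-14 to F52C6.12 (chromosome II, 1869420 to 1930083), where 1000 random sets gave runs of at most 3. The run includes members of the math and bath families, so for those genes reads placed on other copies stay open, and a difference of the mutations themselves was not tested.

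Summed over these 100 genes, the daf-10 libraries held 94 to 160 reads and the eat-2 libraries 20953 to 28936. The set includes clec-10, K09F6.9, ZC204.12, Y113G7B.12, the catalase gene ctl-1 and cest-29. Some members varied widely over the eat-2 libraries, such as cest-29 (1.22 to 22.5 CPM) and C23G10.11 (0.0635 to 5.71 CPM). Such genes may be in the set because their level differs between the eat-2 groups, which was not tested. Of the set 9 genes were called in the interaction for the dve-1 label and 6 in that for atfs-1 RNAi. The eat-2 transcript stood at 0.578 to 1.58 CPM in the daf-10 libraries and at 0.0583 to 0.392 CPM in the eat-2 libraries, and the daf-10 transcript had means of 1.21 and 1.12 CPM.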
